A study of Mus musculus with 72 samples.

How the data were processed

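The 72 arrays hold biotin-labelled RNA from 5 tissues of female C57Bl/6J mice in 3 arms, sham with saline, CLP with saline (CLP/saline) and CLP with MSCs (CLP/MSC), per the labels' protocols. MSCs of male mice, used at passages 8 to 11, or saline were infused at 6 hours and tissues were collected at 28 hours. The series design names 4 animals per group, while liver, kidney, heart and lung each have 5 arrays per arm. The tissue was taken from the source name and the arm from the sample record. The tissue characteristic of 62 arrays names another tissue than the source name, and the mean of the marker genes fixed for each tissue was compared between tissues in every array, on levels normalized apart for spleen and not jointly as planned.

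Both deposited tables hold log2 intensities that the authors had already normalized, as judged from the values, because within each of 2 sets of arrays, the 12 spleen and the 60 others, every array has the same quantiles (largest SD of a quantile 0.000619 and 0.000451 log2). The method behind this normalization and any background correction are not given in the sources used here. The series matrix differs from the other table by 1 constant per probe and set, so that both sets have the same mean for each probe. Its array medians lie between 5.64 and 5.72 in the 60 arrays and between 5.72 and 5.74 in spleen. The constants, with a median absolute size of 0.195 in the 60 arrays, were added back from the other table, which gives medians of 5.49 and 5.83 and leaves every difference within a tissue as it was. In the other table the order of the header held for 22504 of 45255 probes and another order of the tissues for 22751, found by matching sorted values within 0.01 log2, and 0 probes match neither. Of 45281 probes, 18 in the series matrix and 26 in the other table had missing or broken values, and 8 lines of the latter name no probe. Levels in spleen and in other tissues were normalized apart, and all tests of an arm compare arrays within a tissue. The scale (log2) was read from the range of the values, and signal over background on the scanner is unknown.

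Of the spleen arrays 7 stand under another name in the other table than in the sample record, and for 2 of them the arm differs. The array recorded as sham s3 carries a CLP/MSC column name and the array recorded as MSC8 a sham one. Both were left out of the main analysis, a choice made after the files were seen. The mouse numbers of liver, kidney, heart and lung arrays are those of the deposited descriptions, with S for sham, C for CLP/saline and M for CLP/MSC.

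The plan, written before the data were examined, was a background correction with control probes or detection p-values. Neither was in the tables used here and the values were already normalized, so no further background correction or normalization was done. As a substitute for detection p-values, chosen after the files were seen and blind to the arm, a probe's detection p on an array was the share of 1499 olfactory and vomeronasal receptor probes at or above its value. A probe was kept in a tissue if this p was under 0.05 in at least 4 arrays. The level a probe had to reach on an array lay between 5.52 and 6.12 (median 5.76), which serves as the floor of detection, and changes of probes near it are understated. The fitted genes numbered 10521 in liver, 11768 in kidney, 11425 in heart, 12111 in lung and 12053 in spleen.

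Probes were named from the platform annotation. Of the probes used, 34873 had 1 gene symbol, 18 several and 10364 none, and only the first kind was used. For 34795 the symbol was looked up by gene ID in the reference table, with 0 changes, giving 19057 genes. The probe with the highest mean over all arrays stood for a gene. No coordinates are given, because no genome build is named in the sources used here.

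In each tissue limma (version 3.58.1, with statmod 1.5.0, R 4.3.3) was fitted to all 3 arms, which share an estimate of the spread, followed by eBayes and Benjamini-Hochberg adjustment over the genes of the tissue, at 0.05. The arms were compared in all 3 pairs. A standard error in the text is that of the limma fit, and an SD is that of the arrays of an arm. Of 42 gene lists with 1157 symbols written before the data were examined, 1065 symbols had a probe. The 41 lists other than the Y-linked one were tested by camera in limma with its preset correlation of 0.01, two-sided, where at least 5 members were measured, and again with an estimated correlation and by fry, which asks if members move on balance in a direction and does not compare a list with other genes. A count adjusted over the list alone is the number of members past 0.05 after adjustment over that list.

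The genes named in the text follow a rule written before the data were examined. For each tissue, and for CLP/saline against sham and CLP/MSC against CLP/saline, it takes the 4 largest increases and the 4 largest decreases among genes past the threshold whose arms do not overlap. It adds, for each passing list, up to 2 members past the threshold in the direction of the list with the smallest p. It also takes the genes past the threshold in the same direction in all 5 tissues, up to the 10 with the largest mean change, and every detected Y-linked gene. Marker genes such as Scgb1a1, Apoa1 and Myl2 were taken from the tissue marker list.

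Among genes called in CLP/saline against sham, the share whose CLP/MSC difference had the opposite sign was set against 100 simulated data sets with no MSC effect and against all splits of the CLP/saline arrays into separate parts. Differences between tissues were tested in limma on 70 arrays and 9273 genes, with the mouse as a random block, as contrasts of a tissue with the mean of the other 4. This model takes a shared spread per gene from all tissues. The mean level of the Y-linked genes was compared by an exact permutation test of CLP/MSC against the other arrays. Mouse numbers are shared by the arrays of liver, kidney, heart and lung, which come from the same animals by the labels. After subtraction of the group means, arrays of the same mouse in different organs correlated at a mean of 0.197 (70 of 90 pairs over 0.1) and those of other mice of the arm at -0.0474. The mouse correlation in the joint fits of these organs was 0.156 to 0.173, and 0.213 in the model of all tissues. Results of a single organ with the mouse as a block come from these joint fits, which also pool the spread over the organs. A move of such a result can thus not be put down to the block alone.

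Replicate arrays of an arm correlated between 0.893 and 0.995, and no pair was alike enough to be an array deposited more than once (smallest SD of a pair's differences 0.206 log2). The scripts were tested on simulated data with known changes. At a change of 1 log2 the CLP/saline against sham fit found 65.7% of changed genes in liver, 85.1% in kidney, 73.1% in heart, 92.5% in lung and 53.7% in spleen. The CLP/MSC against CLP/saline fit found 79.1%, 77.6%, 79.1%, 98.5% and 65.7% in the same order. Of the calls in these simulations 8.15%, 2.63%, 3.79%, 3.73% and 5.05% were false in the former fit and 6.47%, 5.41%, 3.65%, 5.26% and 6.61% in the latter. The simulated noise was drawn independently for each gene and array, whereas genes of a real array deviate together. These shares thus check the scripts and do not give the power or error rate of the fits on the real arrays.

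Alternatives fixed before the data were examined were the series matrix levels, joint normalization of all arrays, no filter and a stricter filter (p under 0.01 in at least 8 arrays), the mean of all passing probes, a fit of only both compared arms, eBayes with trend and robust options, array weights, each array left out, the mouse as a block or not, and the list tests above. Those added after the files were seen were all 12 spleen arrays under either set of names, omission of the 11 arrays holding transcripts of another organ over 4 log2 above the tissue median, cyclic loess, and the model of tissues without spleen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.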

Results

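Gene expression was measured on Illumina bead arrays in spleen, liver, kidney, heart and lung of female C57Bl/6J mice after cecal ligation and puncture (CLP), an operation that opens the cecum and starts a bacterial infection of the abdomen, or after a sham operation. Saline or cultured mesenchymal stem cells (MSCs) from male mice were infused 6 hours after the operation, and tissues were collected at 28 hours. The stated purpose was to find the molecular changes that accompany MSC treatment of mice with CLP. The 72 arrays fell into 15 groups, 3 arms in each of 5 tissues. Liver, kidney, heart and lung each had 5 sham, 5 CLP/saline and 5 CLP/MSC arrays, named as deposited by mouse number and letter, and the same mouse numbers recurred in these 4 organs. For 2 of the 12 spleen arrays the deposited tables gave different arms, so the spleen comparisons used 3 sham, 4 CLP/saline and 3 CLP/MSC arrays. Values are log2 intensities normalized by the authors, and the number of arrays limits their precision. Changes below are differences of log2 means with the standard error (SE) of the limma fit, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05.

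The tissue of each array was checked with marker genes, because the tissue characteristic in the sample records differed from the source name for 62 of the 72 arrays. In 72 of 72 arrays the markers of the tissue in the source name were the highest, on levels normalized apart in spleen and in the other tissues. Heart markers averaged 14.44 in heart arrays (range 14.04 to 14.78, n = 15) and between 4.89 and 6.96 in the other tissues. Transcripts of another organ stood over 4 log2 above the tissue median in 11 arrays. Scgb1a1, a secretory protein of airway club cells, reached 12.64 to 15.28 in heart arrays 78S, 34C_CLP, 37C_CLP, 107C_CLP and 16M_MSC, against a heart median of 7.66. The liver transcript Apoa1 stood at 13.65 in kidney array 78S, 11.79 in heart array 61M_MSC and 10.08 in lung array 16M_MSC. The heart transcript Myl2 stood at 9.03 in liver array 22S and 8.95 in liver array 101M_MSC, and Scgb1a1 at 9.23 in kidney array 24C_CLP.

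**Figure D1:**
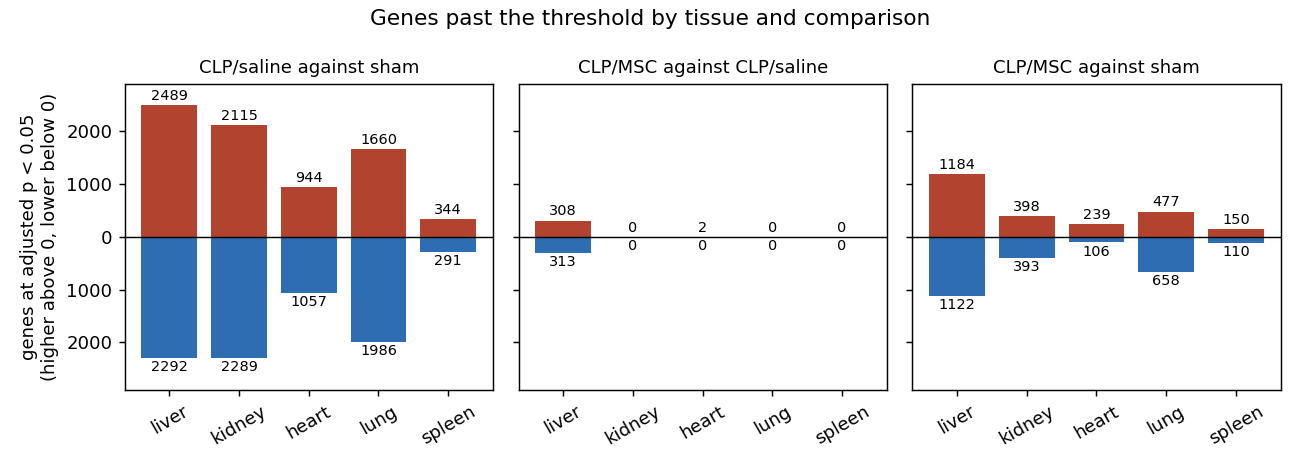
Number of genes at an adjusted p under 0.05 (y axis, genes higher above 0 and lower below 0) in each tissue (x axis) for the 3 comparisons; the figures at the bars are the counts. CLP/saline against sham gave 4781 genes in liver and 635 in spleen, and CLP/MSC against CLP/saline gave 621 in liver, 2 in heart and 0 in kidney, lung and spleen.

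The first comparison, CLP/saline against sham, gives the response to the injury itself. In liver, most unfolded protein response genes and some of the inflammatory lists rose, while some genes of bile acid, drug and amino acid metabolism fell. Cd14, the co-receptor for bacterial lipopolysaccharide, rose by 6.77 ± 0.56 (log2 ± SE, n = 5 and 5), from 7.95 ± 0.35 to 14.72 ± 1.13 (mean ± SD). The cell cycle inhibitor Cdkn1a rose by 5.65 ± 0.41, the acute phase protein Saa3 by 5.42 ± 0.27 and Psat1, an enzyme of serine synthesis, by 4.58 ± 0.69. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 6.89 ± 0.51. Keg1 changed by -5.22 ± 0.65 and the bile acid transporter Slco1b2 by -4.88 ± 0.94. BC048644 fell from 11.57 ± 0.29 to 6.17 ± 1.49 (mean ± SD, n = 5 and 5), but changed by 0.17 (adjusted p = 0.562, limma) with the other probe that the centred levels of the authors' series matrix would choose for it. In all, 2489 genes were higher and 2292 lower among 10521 tested.

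Among the gene lists in liver, 21 of 25 unfolded protein response genes rose and none fell (21 adjusted over the list alone), with the chaperone Hsp90b1 at 2.27 ± 0.27 and Creld2 at 3.35 ± 0.47. Of 18 neutrophil markers, 13 rose and 2 fell, with Cd177 at 2.11 ± 0.21 and Ngp at 3.02 ± 0.31. Of 22 cytokine and NF-kB feedback genes, 14 rose and 3 fell, among them Irak3 at 3.71 ± 0.32 and Nfkbiz at 1.84 ± 0.20. Acute phase proteins rose for 9 of 22 members, with Il1rn, the interleukin-1 receptor antagonist, at 4.43 ± 0.49. Endothelial activation genes rose for 9 of 18 and fell for 2, with the adhesion molecule Icam1 at 1.74 ± 0.25 and Adamts1 at 1.75 ± 0.32. The p53 and apoptosis list had 9 of 24 higher and 1 lower, including Bcl2l1 at 1.46 ± 0.27. In the tubular injury list 9 of 16 members rose and 1 fell, with Cdkn1a and the protease inhibitor Timp1 (3.31 ± 0.35) among those higher, genes that many cell types express. Of 37 cytochrome P450, bile acid and drug metabolism genes, 32 fell and none rose (33 adjusted over the list alone), including Fmo5, which fell by 2.78 ± 0.34. Gluconeogenesis, urea cycle and amino acid genes fell for 20 of 27 and rose for 1, with Prodh at -2.53 ± 0.29 and Agxt at -2.41 ± 0.34. Complement genes fell for 15 of 24, with the lectin Mbl2 at -2.03 ± 0.38 and Cd59a at -1.17 ± 0.23. Oxidative phosphorylation genes fell for 23 of 56, with Sdhb at -0.91 ± 0.13 and Ndufs8 at -1.04 ± 0.19, and rose for 2. The immunoproteasome genes Psmb9 and Psmb8 changed by -2.13 ± 0.29 and -1.31 ± 0.22 in an interferon list in which 12 of 31 fell. MHC class II genes fell for 4 of 14, including H2-DMa at -1.60 ± 0.21 and H2-DMb2 at -1.51 ± 0.25. Of 18 hepatocyte markers 7 fell and 1 rose, with Ahsg at -0.86 ± 0.18 and Apoc3 at -0.92 ± 0.19. Both lost the call in the joint fit with the mouse as a block and pooled spread (adjusted p = 0.291 and 0.17, limma). That spread includes kidney array 78S, where Ahsg stood at 12.73 against a kidney median of 6.39. Whether such arrays of other organs ended the calls was not tested. Of 15 circadian clock genes 8 fell and 2 rose, led by Dbp at -4.11 ± 0.34 and Usp2 at -3.70 ± 0.32. Of 12 erythroid markers 7 fell and 1 rose, with the carbonic anhydrases Car2 and Car1 at -1.45 ± 0.22 and -1.97 ± 0.33. These 16 lists passed camera with its preset correlation at adjusted p between 3.85e-11 and 0.0493. With an estimated correlation none passed (adjusted p = 0.251 to 0.48).

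In kidney, most tubular injury and neutrophil genes of the lists rose, as did some of the other inflammatory lists, and some genes of transport and energy metabolism fell. Lcn2, a neutrophil and epithelial protein that binds bacterial siderophores, rose by 6.42 ± 0.50 (n = 5 and 5), from 8.93 ± 0.94 to 15.34 ± 0.57 (mean ± SD). Saa3 rose by 6.19 ± 0.45, the keratin Krt20 by 5.72 ± 1.11 and the formyl peptide receptor Fpr2 by 4.88 ± 0.29. D630023F18Rik changed by -3.69 ± 0.57, the anion exchanger Slc4a1 by -2.94 ± 0.57, Pvalb by -2.87 ± 0.61 and Nat8f1 by -2.84 ± 0.67. Of 11768 genes, 2115 were higher and 2289 lower. Tubular injury genes rose for 15 of 17 members (15 adjusted over the list alone), with Timp1 at 3.98 ± 0.32. Neutrophil markers rose for 14 of 18, with Ngp at 2.16 ± 0.23, and cytokine and NF-kB feedback genes for 15 of 20, with Socs3 at 4.04 ± 0.51 and Irak3 at 1.82 ± 0.24. Of 22 chemokines 9 rose and 2 fell, with the neutrophil attractant Cxcl1 at 4.69 ± 0.67 and Ccl3 at 2.21 ± 0.33. The acute phase list had 10 of 20 higher, the p53 and apoptosis list 14 of 25 and 1 lower, with Casp4 at 1.78 ± 0.25 and Cdkn1a at 4.33 ± 0.62, and the glucocorticoid list 10 of 23 and 1 lower, with Pdk4 at 4.04 ± 0.52. Unfolded protein response genes rose for 12 of 25, with Chac1 at 3.50 ± 0.51 and Xbp1 at 1.42 ± 0.24. Endothelial activation genes rose for 8 of 18, with Icam1 at 1.65 ± 0.22 and P-selectin, Selp, at 2.33 ± 0.35. Renal tubular transporters fell for 17 of 33 and rose for 1 (17 adjusted over the list alone), with the organic anion transporter Slc22a8 at -1.66 ± 0.25 and Slc6a19 at -0.82 ± 0.14. Oxidative phosphorylation genes fell for 27 of 57, with Ndufs8 at -0.86 ± 0.19 and Ndufc1 at -0.83 ± 0.18 and 1 member higher, and citrate cycle genes for 9 of 17, with Idh2 at -0.84 ± 0.18 and Dlat at -0.72 ± 0.17. In the gluconeogenesis, urea cycle and amino acid list 11 of 20 fell, with Cbs at -1.49 ± 0.26 and Asl at -1.20 ± 0.23. MHC class II genes fell for 7 of 13 and rose for 2, with H2-DMa at -1.06 ± 0.18 and H2-Eb1 at -1.26 ± 0.24. These 14 lists passed camera at adjusted p between 4.36e-08 and 0.0239, and none with an estimated correlation (adjusted p = 0.408 to 0.623). Without arrays 78S and 24C_CLP, which held transcripts of other organs, 2713 genes were called.

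In heart, some members of the acute phase, neutrophil and monocyte lists rose. Saa3 rose by 7.93 ± 0.33 (n = 5 and 5), from 6.69 ± 0.84 to 14.62 ± 0.26 (mean ± SD), Lcn2 by 6.22 ± 0.51, the chitinase-like protein Chil1 by 5.59 ± 0.39 and Saa1 by 5.08 ± 1.12. Ky, a gene needed for skeletal muscle upkeep, changed by -3.24 ± 0.43, Lsmem1 by -2.87 ± 0.47, Snai3 by -2.66 ± 0.41 and Fcrls by -2.65 ± 0.58. Of 11425 genes, 944 were higher and 1057 lower. Acute phase proteins rose for 12 of 19 (14 adjusted over the list alone), neutrophil markers for 12 of 19 with Fpr2 at 4.94 ± 0.33 and Lrg1 at 3.15 ± 0.33, and cytokine and NF-kB feedback genes for 16 of 27 with Nfkbiz at 2.72 ± 0.24 and Irak3 at 1.85 ± 0.20. Monocyte and macrophage markers rose for 9 of 22, with the Fc receptor Fcgr4 at 3.71 ± 0.23 and Clec4d at 3.43 ± 0.34, and phagocytosis genes for 11 of 32 with 2 lower, Fcgr2b rising by 1.64 ± 0.20. Chemokines rose for 10 of 23 and fell for 1, with Ccl19 at 2.77 ± 0.28 and the B cell attractant Cxcl13 at 4.81 ± 0.71. Metallothionein and oxidative stress genes rose for 8 of 23, with heme oxygenase, Hmox1, at 3.95 ± 0.45 and Mt2 at 3.56 ± 0.46, and the glucocorticoid list had 10 of 22 higher. Endothelial activation genes rose for 7 of 22 and fell for 1, with Selp at 3.82 ± 0.52 and Adamts9 at 2.14 ± 0.30. Coagulation genes rose for 2 of 16, the plasminogen activator Plat at 1.60 ± 0.27 and the urokinase receptor Plaur at 1.95 ± 0.36, and 1 fell. Casp4 rose by 1.89 ± 0.23 and Cdkn1a by 2.90 ± 0.38 in the p53 and apoptosis list, of which 6 of 23 rose, and Timp1 by 3.40 ± 0.39 in the tubular injury list, of which 6 of 15 rose. Cardiac contractile and electrical genes fell for 7 of 30, with Myh7 at -1.64 ± 0.27 and phospholamban, Pln, at -1.55 ± 0.34. Only Ndufa8, at -0.46 ± 0.14, was called among 57 oxidative phosphorylation genes, and its call ended without the filter on dim probes (adjusted p = 0.0676, limma), with only both compared arms in the fit (0.0546) and without any 1 of 9 arrays (up to 0.0954). These 14 lists passed camera at adjusted p between 1.87e-12 and 0.0176, and none with an estimated correlation (adjusted p = 0.105 to 0.859). The gene count was 3379 without sham array 78S, in which Scgb1a1 and T cell transcripts were high, and 3628 without the 6 heart arrays holding transcripts of other organs. It was 1271 with only the compared arms in the fit and 3809 with array weights.

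In lung, some members of the acute phase and neutrophil lists rose and some of the lymphocyte lists fell. Saa3 rose by 7.56 ± 0.23 (n = 5 and 5), from 7.18 ± 0.44 to 14.74 ± 0.42 (mean ± SD), Saa1 by 6.56 ± 0.61, the neutrophil granule protein Ngp by 5.57 ± 0.29 and the acute phase protein Orm1 by 4.53 ± 0.62. Fcmr, the IgM Fc receptor of B cells, changed by -3.63 ± 0.27, Ly6d by -2.56 ± 0.16, Aard by -2.53 ± 0.39 and the matrix protein Ogn by -2.49 ± 0.45. Of 12111 genes, 1660 were higher and 1986 lower, or 2062 in all with the mouse as a block. B cell markers fell for 16 of 18 (17 adjusted over the list alone), with the antigen receptor component Cd79b at -2.28 ± 0.12. NK and cytotoxic markers fell for 8 of 12, with Klre1 at -1.70 ± 0.14 and Ctsw at -1.25 ± 0.14. Both lists also passed with an estimated correlation (adjusted p = 0.0255 and 0.0475). T cell markers fell for 8 of 19, with Cd3g at -1.53 ± 0.20 and Cd2 at -1.40 ± 0.18. Cd3g lost its call in the joint fit with the mouse as a block and pooled spread (adjusted p = 0.141, limma). That spread includes sham heart array 78S, with a T cell list mean of 10.32, and whether this ended the call was not tested. MHC class II genes fell for 12 of 18 and rose for 1, with H2-Ob at -2.32 ± 0.15 and H2-Oa at -1.83 ± 0.12. Endothelial junction genes fell for 13 of 29 and rose for 3, with the connexin Gja5 at -1.71 ± 0.22 and the angiopoietin receptor Tek at -1.25 ± 0.21. Neutrophil markers rose for 16 of 24, with Fpr2 at 2.02 ± 0.20, acute phase proteins for 11 of 18 with Lcn2 at 2.59 ± 0.19, and chemokines for 12 of 23, with 3 lower, Cxcl13 at 4.34 ± 0.30 and Ccl9 at 2.01 ± 0.20. Cytokine and NF-kB feedback genes rose for 12 of 27 and fell for 1, with Nfkbiz at 2.02 ± 0.20 and the decoy receptor Il1r2 at 2.93 ± 0.39, and monocyte and macrophage markers rose for 11 of 22 and fell for 2, with Fcgr4 at 1.87 ± 0.22 and Cd14 at 1.77 ± 0.28. The glucocorticoid list had 12 of 22 higher, with Pdk4 at 2.64 ± 0.27, and the oxidative stress list 12 of 23 higher and 3 lower, with Mt1 at 1.59 ± 0.17 and Sqstm1 at 0.73 ± 0.11. In the p53 and apoptosis list 8 of 25 rose, with Cdkn1a at 2.53 ± 0.31 and Casp4 at 0.88 ± 0.18, and in the tubular injury list 6 of 16 rose and 2 fell, with Timp1 at 2.91 ± 0.30. In total 14 lists passed camera at adjusted p between 1.91e-16 and 0.0492. The other 12 did not pass with an estimated correlation (adjusted p = 0.162 to 0.479).

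In spleen, some members of the acute phase, chemokine and neutrophil lists rose, and some of the lymphocyte, MHC class II and cholesterol synthesis lists fell. Saa3 rose by 6.20 ± 0.55 (4 CLP/saline and 3 sham arrays), from 7.18 ± 0.76 to 13.38 ± 0.50 (mean ± SD), Lcn2 by 5.53 ± 0.26, AA467197 by 4.87 ± 1.15 and the chemokine Ccl12 by 4.43 ± 0.59. Apol7c changed by -3.58 ± 0.27, the low-affinity IgE receptor Fcer2a of B cells by -3.50 ± 0.68, Clec9a, a receptor of cross-presenting dendritic cells, by -2.58 ± 0.42 and Gpr34 by -2.54 ± 0.52. AA467197 missed the threshold when all arrays were normalized together (adjusted p = 0.0547, limma). Of 12053 genes, 344 were higher and 291 lower. Serpina3n rose by 3.83 ± 0.16 in an acute phase list with 5 of 17 higher (9 adjusted over the list alone). Neutrophil markers rose for 5 of 24, with Lrg1 at 3.67 ± 0.21 and Fpr2 going from 10.33 ± 0.35 to 13.33 ± 0.40 (mean ± SD), chemokines for 4 of 23, with 1 lower and the stromal chemokine Cxcl12 at 1.41 ± 0.11, and cytokine and NF-kB feedback genes for 5 of 28 with Il1r2 at 3.84 ± 0.40 and Il18 at 0.99 ± 0.14. Cxcl12 lost its call when the probes of a gene were averaged (0.51, adjusted p = 0.137, limma). The scavenger receptor Marco rose by 2.11 ± 0.22 and Fcgr4 by 1.49 ± 0.18 among monocyte and macrophage markers, 5 of 22 of which rose. Fkbp5 rose by 2.04 ± 0.30 in the glucocorticoid list (9 of 22 higher), and Gpx3 by 1.82 ± 0.15 and Mt1 by 1.92 ± 0.34 in the oxidative stress list (5 of 21 higher, 1 lower). Cholesterol biosynthesis genes fell for 7 of 18 (12 adjusted over the list alone), with Sqle at -1.24 ± 0.12 and Fdps at -1.60 ± 0.18, and this list also passed with an estimated correlation (adjusted p = 0.044). MHC class II and antigen presentation genes fell for 10 of 20, with Cd209a at -2.13 ± 0.18 and Xcr1 at -1.48 ± 0.16, and NK and cytotoxic markers for 6 of 18, with Xcl1 at -1.70 ± 0.23 and Klrg1 at -1.64 ± 0.22. T cell markers fell for 4 of 21, with Cd247 at -1.18 ± 0.21 and Cd2 at -1.03 ± 0.19, and B cell markers for 2 of 21, Fcer2a and Ly6d, the latter at -2.10 ± 0.44. Of 11 skeletal muscle markers 3 fell, including Tnni2 at -2.27 ± 0.21 and Eno3 at -0.77 ± 0.16. Small numbers of members were called in the p53 list (Mdm2, 0.77 ± 0.19), the glycolysis list (Pkm, 0.65 ± 0.13), the clock list (Per2, 0.73 ± 0.18) and the tubular injury list (Lcn2). Mdm2 lost its call without the filter, with averaged probes, with both compared arms alone and with cyclic loess (adjusted p = 0.0615 to 0.0715, limma) and Per2 without the filter and with a robust, trended variance (0.0677 and 0.0501). No erythroid marker of 24 was called, and 1 of 56 oxidative phosphorylation genes was called higher, although both lists passed in the downward direction. In all 19 lists passed camera at adjusted p between 4.21e-09 and 0.0358. The other 18 did not pass with an estimated correlation (adjusted p = 0.0503 to 0.63).

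The spleen count rested on single arrays and on the names of the arrays. It was 183, 106 and 114 without sham arrays s1, s2 and s4, 2284, 255 and 239 without CLP/saline arrays CLP3, CLP8 and CLP2, and 357 and 1443 without CLP/MSC arrays MSC4 and MSC7, which share the estimate of spread. Of the 39 named genes, 18 lost their call without at least 1 array, AA467197 and Per2 without any 1 of 8 (adjusted p up to 0.149 and 0.158, limma). With all 12 spleen arrays it was 0 under the arms of the sample records and 1737 under the column names of the other table, and no named gene passed under the records (adjusted p = 0.389 to 0.408, limma). The records count s3, with Saa3 at 12.63, as sham and MSC8, with Saa3 at 7.46, as CLP/MSC. Array weights on the 10 arrays gave 3387.

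Across tissues, 68 genes rose and 19 fell in all 5 of them among 9273 genes tested in every tissue. Saa3 had the largest mean change, 6.66, followed by Lcn2 at 4.43, Cd14 at 3.75, Fpr2 at 3.49, AA467197 at 3.22, Cxcl13 at 3.17, Pdk4, a kinase that restrains glucose oxidation, at 3.08, the cytokine signalling inhibitor Socs3 at 3.01, and Slc10a6 and the metallothionein Mt2 at 2.91 each. Cd14, AA467197, Cxcl13, Pdk4, Socs3, Slc10a6 and Mt2 each lost the spleen call without at least 1 array. In a model of all tissues with the mouse as a random block, the named changes differed in size between tissues except that of AA467197. Its differences between tissues had adjusted p = 0.0731 to 0.968 (limma). Cd14 rose in liver by 3.78 more than in the mean of the other 4 tissues (limma, adjusted p = 6.83e-08), and the Lcn2 difference there was -3.78. The Lcn2 level in CLP/saline liver was 16.00 ± 0.03 (SD, n = 5), at the top of the scale, which bounds its change there and every Lcn2 difference between tissues that includes liver. In liver, 3756 genes had a CLP effect that differed from the mean of the other 4 tissues, against 1188 in kidney, 1108 in heart, 776 in lung and 620 in spleen. The model takes a shared spread per gene from all tissues, whose arrays vary to unlike degrees, so these counts do not rank the tissues. The kidney count was 789, 713, 760 and 2036 without kidney arrays 24C_CLP, 35C_CLP, 37C_CLP and 107C_CLP, and the lung count 492 and 508 without lung arrays 24C_CLP and 34C_CLP. The spleen count was 378, 267 and 296 without s1, s2 and s4, 1103, 318 and 312 without CLP3, CLP8 and CLP2, and 250 with all 12 arrays under the records. Without the mouse as a block the counts in kidney, heart and lung were 765, 634 and 432, and lung gave 1403 when spleen was left out.

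**Figure D2:**
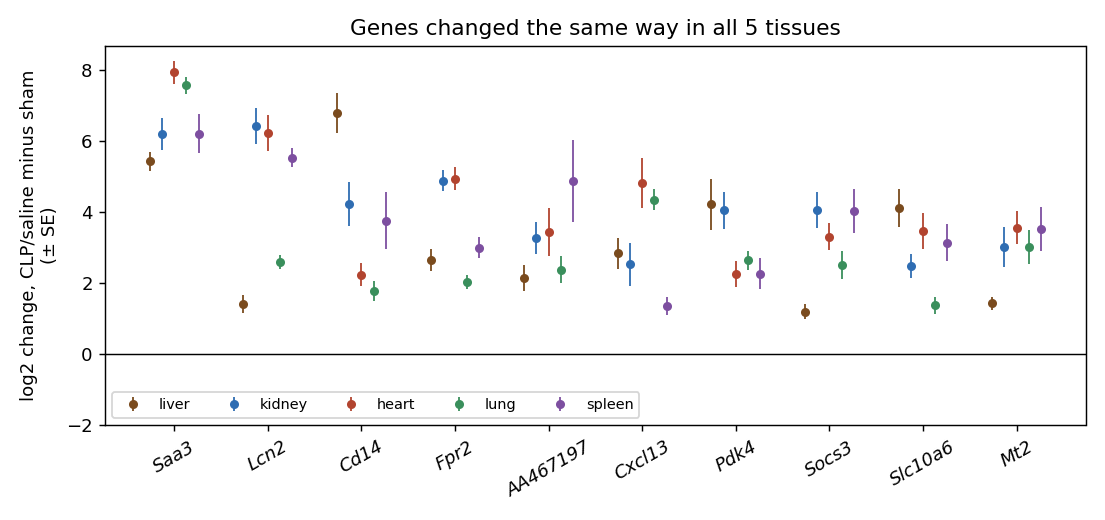
Change in CLP/saline minus sham (y axis, log2, points with bars of 1 SE) for the 10 genes with the largest mean change among those called in the same direction in all 5 tissues (x axis), with a colour per tissue; n = 5 and 5 arrays, in spleen 4 and 3. Every point lies above 0, and Saa3 ranges from 5.42 in liver to 7.93 in heart.

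The second comparison, CLP/MSC against CLP/saline, is the one the study was designed for. In liver, 308 genes were higher and 313 lower. The neutrophil chemokine Cxcl2 changed by -1.98 ± 0.36 (log2 ± SE, n = 5 and 5), from 9.06 ± 0.74 to 7.08 ± 0.72 (mean ± SD), the phosphodiesterase Pde4b by -1.68 ± 0.35, 1700109H08Rik by -1.28 ± 0.30 and the MHC class II gene H2-Ab1 by -1.27 ± 0.30. Zfp750 rose by 1.72 ± 0.37, D630004K10Rik by 1.43 ± 0.34, Mettl7b by 1.42 ± 0.36 and Ikbip by 1.41 ± 0.23. Endothelial activation genes fell for 5 of 18 (7 adjusted over the list alone), with E-selectin, Sele, at -1.60 ± 0.31 and Angpt2 at -0.85 ± 0.20. Fatty acid oxidation and ketogenesis genes rose for 3 of 26 (6 adjusted over the list alone), with Hadhb at 0.83 ± 0.20 and the ketone body enzyme Bdh1 at 1.82 ± 0.46. In the gluconeogenesis, urea cycle and amino acid list 2 of 27 rose (4 adjusted over the list alone), Pck1, an enzyme of glucose synthesis, by 2.17 ± 0.49 and Kmo by 1.40 ± 0.35. Pmvk rose by 1.52 ± 0.42 as the 1 member called of 18 cholesterol biosynthesis genes (12 adjusted over the list alone), and Cox6c by 0.54 ± 0.15 among 56 oxidative phosphorylation genes (0 adjusted over the list alone). The 5 lists passed camera at adjusted p between 5.37e-05 and 0.00558, and none with an estimated correlation (adjusted p = 0.697 for each).

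The named liver genes lay just inside the threshold (adjusted p = 0.0441 to 0.0455, limma), and each lost its call when any array but 107C_CLP was left out (up to 0.119). The count of 621 moved likewise. It was 3327 without CLP/saline mouse 107C_CLP and 0 without any other of the 15 liver arrays, sham arrays included. It was also 0 without arrays 22S and 101M_MSC together, 0 without the filter on dim probes, 0 with only both compared arms in the fit, 939 with a stricter filter, 2895 with array weights and 2752 with the mouse as a random block. Averaging probes ended the call of 1700109H08Rik (adjusted p = 0.0572) and cyclic loess that of Cox6c (0.0506, limma). The number of lists was 9 without 107C_CLP, 8 without 16M_MSC and 8 with the series matrix levels (4 higher and 4 lower, against 4 and 1).

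**Figure D3:**
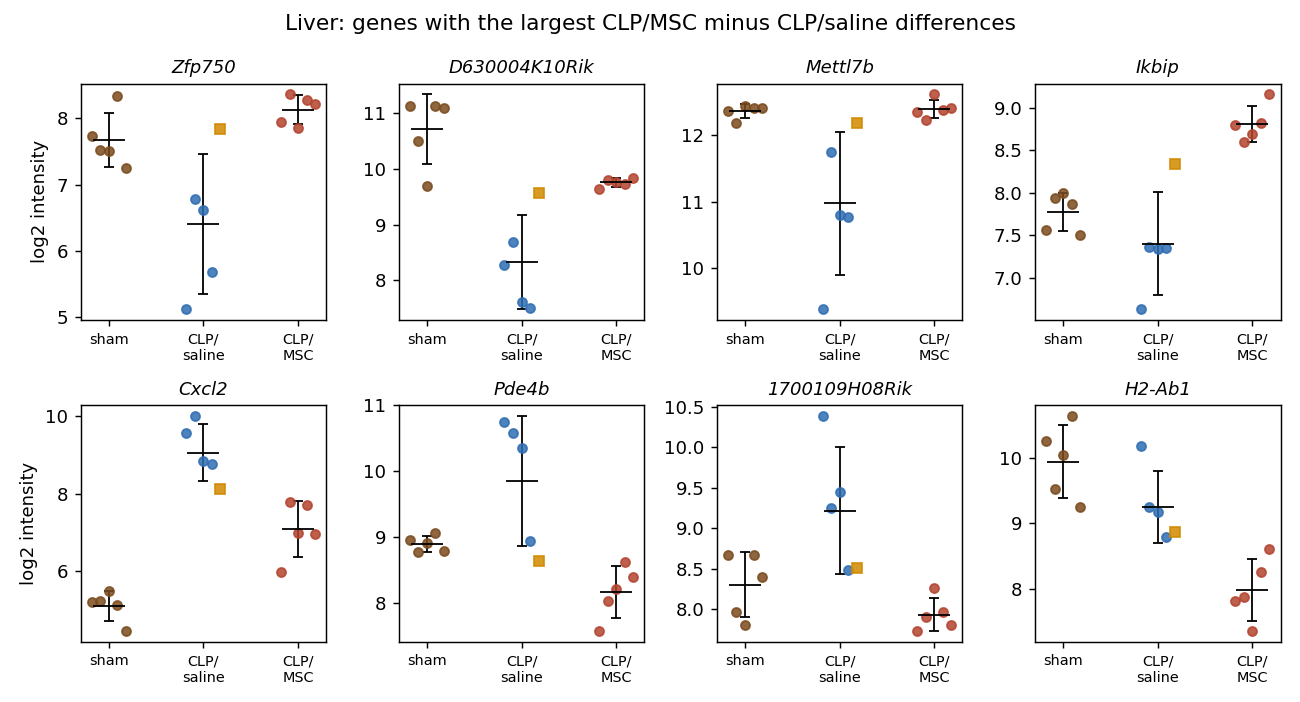
Log2 intensity (y axis) in liver of the 8 genes with the largest called CLP/MSC minus CLP/saline differences among those whose arrays do not overlap, by arm (x axis); each point is a mouse, the bars are mean ± SD (n = 5), and the square is CLP/saline mouse 107C_CLP. The CLP/saline and CLP/MSC points do not overlap, as the choice of genes requires, and 107C_CLP is the CLP/saline point nearest to the CLP/MSC arm for Zfp750, D630004K10Rik, Mettl7b, Ikbip, Cxcl2 and Pde4b.

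In kidney, lung and spleen no gene passed the adjusted threshold in limma, while 3027, 2970 and 387 genes had an unadjusted p under 0.05. Without mouse 107C_CLP the counts were 3615 in kidney and 2646 in lung, and kidney gave 1 without 16M_MSC and 2 without 100M_MSC. With the mouse as a random block they were 1215 and 158, and with array weights 2997 and 1544. The spleen count stayed at 0 in each alternative run. In heart 2 genes passed, Zranb3, a DNA repair helicase, at 1.54 ± 0.23 and the transcriptional coregulator Cited2 at 1.05 ± 0.16 (adjusted p = 0.0351 each, limma), and 1879 had an unadjusted p under 0.05. Both calls ended without the filter (adjusted p = 0.0538 each, limma), with averaged probes (0.0662 and 0.0715) and with both compared arms alone (0.0627 each). The heart count was 852 without mouse 107C_CLP, 535 without sham mouse 78S, 1 without CLP/MSC mouse 61M_MSC, 2 without 21S or 77S and 0 without any other array. It was 1502 without the 6 heart arrays holding transcripts of other organs, 925 with array weights, 558 with the mouse as a block, 20 with a stricter filter and 1 with cyclic loess. Those 6 arrays include 107C_CLP, 78S and in all 3 CLP/saline and 2 CLP/MSC arrays. The rise to 1502 can thus not be told apart from the omission of 107C_CLP and 78S.

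Several gene lists shifted between the CLP arms under the preset correlation, with few or no members called singly. None of those in kidney, heart, lung and spleen passed with an estimated correlation (adjusted p = 0.581 to 0.99), and 55, 47 and 83 of 100 splits of the arrays in the first 3 tissues and 35 of 35 in spleen gave as many lists. In kidney the cytokine and NF-kB feedback list was lower (median change -0.47, 5 of 20 lower adjusted over the list alone), as were endothelial activation (-0.34, 7 of 18), adipocyte markers (-0.68, 4 of 11), the interferon list (-0.21, 4 of 31), tubular injury (-0.55, 0 of 17) and cell cycle (-0.23, 6 of 26, with 2 higher). The adrenal markers, of a gland next to the kidney, were higher (median 1.52, 7 of 10), as were the gluconeogenesis, urea cycle and amino acid list (0.34, 3 of 20) and oxidative phosphorylation (0.12, 0 of 57). With an estimated correlation these 9 kidney lists had adjusted p = 0.815 to 0.856, and 5 passed with the preset one without array 24C_CLP. In heart the median was lower for cytokine and NF-kB feedback genes (-0.35, 6 of 27 lower adjusted over the list alone), tubular injury (-0.33, 2 of 15) and, with no member called, MHC class II (-0.51), B cell markers (-0.53), endothelial activation (-0.27), the p53 list (-0.18) and extracellular matrix (-0.10). It was higher for fatty acid oxidation (0.38), citrate cycle (0.24), oxidative phosphorylation (0.19) and cardiac contractile genes (0.21, 1 of 30). The B cell list mean was 8.10 in heart array 107C_CLP and 5.51 to 7.12 in the others, and the median change was 0.11 without the arrays holding transcripts of other organs (camera within limma, adjusted p = 0.528). The 11 heart lists did not pass with an estimated correlation (adjusted p = 0.797 to 0.853), and 7, 5 and 4 passed without arrays 34C_CLP, 107C_CLP and 44M_MSC. In lung the endothelial junction list was higher (median 0.35, 14 of 29 higher and 2 lower adjusted over the list alone), as were the cytochrome P450 list (0.21, 5 of 15) and hepatocyte markers (0.60, 0 of 11), which moved with the liver transcript Apoa1 in CLP/MSC array 16M_MSC. Cell cycle (-0.21, 9 of 29), cholesterol biosynthesis (-0.21, 6 of 19) and T cell markers (-0.26, 1 of 19) were lower in lung. With an estimated correlation these 6 lung lists had adjusted p = 0.581 to 0.99. In spleen the erythroid (0.60) and platelet (0.27) markers were higher and the clock list (-0.22) lower with no member called (adjusted p = 0.97 each with an estimated correlation), and 5, 7 and 9 lists passed without CLP3, MSC4 and MSC7.

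Among the genes that CLP changed, the sign of the MSC difference was set against that of the CLP difference. The share with a CLP/MSC minus CLP/saline difference of opposite sign was 86.9% of 4781 genes in liver, 92.5% of 4404 in kidney, 93.6% of 2001 in heart, 90.2% of 3646 in lung and 76.7% of 635 in spleen. Both differences contain the CLP/saline arrays, so opposite signs arise without any MSC effect. Simulated data with the CLP effects and no MSC effect gave mean shares of 54.4%, 54.8%, 61.9%, 60.3% and 59.2% in the same order of tissues. They shuffled the deviations of the arrays among all arms. In liver, kidney and lung the CLP/saline arrays varied most (largest SD of a pair's differences 0.962, 0.835 and 0.655). The simulated shares, correlations and covariances may thus understate there what arises without an MSC effect. A share as high as observed occurred in 8, 2, 1, 2 and 28 of 100 simulations. When the CLP/saline mice were split so that each difference used separate mice, the mean shares were 79.6%, 80.8%, 82.5%, 78.9% and 51.9%. Single splits ranged from 69.3 to 86.3%, 57.4 to 94.0%, 67.6 to 91.0%, 62.4 to 85.6% and 36.8 to 66.2%. No spread expected without an MSC effect was computed for these splits. Across genes, which are not independent replicates, the correlation of both differences was -0.66 in liver against -0.08 simulated, -0.72 against -0.07 in kidney, -0.66 against -0.20 in heart, -0.65 against -0.17 in lung and -0.50 against -0.15 in spleen. The covariance was -0.27 in liver against -0.03 simulated, -0.18 against -0.02 in kidney, -0.13 against -0.03 in heart, -0.09 against -0.02 in lung and -0.08 against -0.05 in spleen.

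Genes with an MSC effect unlike the mean of the other 4 tissues numbered 1073 of 9273 in liver, the highest count. The counts were 13 in kidney, 47 in heart, 15 in lung and 0 in spleen (775 at an unadjusted p under 0.05, limma). The model takes a shared spread per gene from all tissues. Among CLP/saline arrays, however, the largest SD of a pair's differences was 0.962 in liver and 0.655 in lung. A shared spread may raise the liver count and lower that of lung, so the counts do not rank the tissues. The liver count was 512, 606 and 2214 without liver arrays 35C_CLP, 37C_CLP and 107C_CLP and 614 without the mouse as a block. Without this block the counts were 4 in kidney, 20 in heart, 3 in lung and 1 in spleen. When spleen was left out they were 61 in kidney, 84 in heart and 37 in lung, and kidney also gave 37 with all 12 spleen arrays under the column names. The heart count was 96 without heart array 78S, 115 without liver array 107C_CLP, and 8, 132, 29, 29 and 23 without heart arrays 37C_CLP, 107C_CLP, 44M_MSC, 100M_MSC and 101M_MSC. The spleen count was 52 without CLP3, 28 without liver array 107C_CLP and 1 without liver array 44M_MSC. The kidney count was 654, 149, 4, 4, 8, 5 and 7 without kidney arrays 107C_CLP, 16M_MSC, 24C_CLP, 35C_CLP, 37C_CLP, 61M_MSC and 101M_MSC, and 60 without heart array 78S. It was 22, 56 and 28 without liver arrays 24C_CLP, 107C_CLP and 100M_MSC, 20 without lung array 107C_CLP, and 25 and 21 without spleen arrays CLP3 and MSC7. The lung count moved by over 1.5 times for 41 of 70 arrays left out (0 to 151, the highest without lung array 107C_CLP).

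The third comparison set CLP/MSC against sham. Here 2306 genes differed in liver (1184 higher), 791 in kidney (398 higher), 345 in heart (239 higher), 1135 in lung (477 higher) and 260 in spleen (150 higher), and 14 genes rose and 1 fell in all 5 tissues. In liver 18 of 25 unfolded protein response genes and 14 of 18 neutrophil markers were higher, and 21 of 37 cytochrome P450, bile acid and drug metabolism genes lower. In kidney 11 of 18 neutrophil markers and 7 of 17 tubular injury genes were higher and 9 of 33 tubular transporters lower. In heart 8 of 19 neutrophil markers and 7 of 19 acute phase proteins were higher, the neutrophil list also with an estimated correlation (adjusted p = 0.0457). T cell markers in heart had a median of -1.03 with 0 of 18 called, and the T cell list mean was 10.32 in sham heart array 78S against 6.36 to 7.25 in the other sham arrays. In lung 17 of 24 neutrophil markers were higher and 15 of 18 B cell, 8 of 12 NK and 12 of 19 T cell markers lower, each list also passing with an estimated correlation (adjusted p = 0.0366, 0.00272, 0.00272 and 0.0366), as did fatty acid oxidation, with 6 of 27 higher, and MHC class II, with 11 of 18 lower (0.0358 each). In spleen 6 of 18 cholesterol biosynthesis genes were lower and 5 of 17 acute phase proteins higher (adjusted p = 0.019 and 0.0344 with an estimated correlation). Camera with the preset correlation passed 15, 22, 23, 18 and 20 lists in liver, kidney, heart, lung and spleen. With an estimated correlation the liver lists had adjusted p = 0.225 to 0.512 and the kidney lists 0.138 to 0.518. The other heart lists had 0.0548 to 0.589, the other lung lists 0.06 to 0.401 and the other spleen lists 0.0584 to 0.715. The kidney count was 523, 447 and 468 without sham arrays 21S, 76S and 77S, 1552 without 107C_CLP, and 404, 502 and 512 without 16M_MSC, 61M_MSC and 101M_MSC. The heart count was 201, 191 and 203 without 21S, 76S and 77S, and 200 and 204 without 16M_MSC and 101M_MSC. It was 562 without 78S, with 279 higher and 283 lower. Without the arrays holding transcripts of other organs, 78S among them, it was 519, with 276 higher and 243 lower. With the mouse as a block, heart had 691 genes (418 higher) and lung 460 (212 higher). Array weights gave 3747, 2044, 1714, 1969 and 2685 genes in the order of tissues above, and a fit of only the compared arms 1748 in kidney and 1897 in lung. The spleen count was 121, 79 and 62 without s1, s2 and s4, 74 and 97 without MSC4 and MSC5, and, with all 12 arrays, 0 under the sample records and 1017 under the other column names.

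Transcripts of the Y chromosome were examined because the donor cells were male and the recipients female. For the mean of the detected Y-linked genes, no difference between CLP/MSC arrays and the others passed the test in any tissue. The difference was -0.03 in liver, 0.10 in kidney, -0.02 in heart, -0.03 in lung and -0.16 in spleen (log2, two-sided exact permutation tests, p = 0.798, 0.408, 0.865, 0.666 and 0.383, adjusted p = 0.865 for each of the 5). Uty passed the detection filter in every tissue, Zfy1 in liver and Eif2s3y in heart. These probes were also detected in female mice without donor cells, Uty in 5 of 5 sham arrays of kidney and of lung. Zfy1 was detected in 3 of 5 sham arrays of liver. Detection of these probes is thus no sign of male cells. Averaged over the detected genes of a tissue, mean levels in CLP/MSC and in the other arrays lay between 5.81 and 6.23, beside a detection floor of 5.52 to 6.12, so a small number of donor cells was not detectable at this signal.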

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

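The tests of a swapped label and of failed arrays for mouse 107C_CLP, of lung parenchyma and airway epithelium in heart arrays, and of the spleen array names were chosen after the results were seen, while those of thymus and of other splits of the arrays were written before.

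Single arrays far from the rest of their arm were sought in 553 groups of 4 or 5 arrays, over the named genes and the position of each array between sham and CLP/saline. The measure was the gap between the extreme array and its nearest neighbour, as a share of the range of the group. It passed Dixon's 95% critical value in 44 groups, where chance gives about 1 in 20 (27.65 here) for independent groups, and 22 of the 44 were mouse 107C_CLP. The groups are not independent, as they come from the same mice and from genes named for their changes. The 22 values of 107C_CLP may thus restate the same deviation of this mouse, and 44 cannot be tested against 27.65. In liver, 107C_CLP stood apart for Cd14 (0.821), Cdkn1a (0.86), Psat1 (0.753), Cyp7a1 (0.757), Slco1b2 (0.711), Fmo5 (0.747), Psmb9 (0.777), Ndufs8 (0.723), Fpr2 (0.847), Pdk4 (0.74) and its position (0.898). In kidney it stood apart for D630023F18Rik (0.734), Pdk4 (0.785), Chac1 (0.894) and Xbp1 (0.771), in heart for Mt2 (0.895), Hmox1 (0.836), Fcgr2b (0.811) and its position (0.712), and in lung for Gja5 (0.717), Mt1 (0.796) and Cd2 (0.789). Its Cd14 level in liver was 12.73 beside 14.99 in the nearest CLP/saline array, and its Cyp7a1 level 7.66 beside 5.17.

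The remaining 22 were in other mice. In liver they were BC048644 (0.868) and Pck1 (0.733) in 21S, Keg1 (0.755) in 76S, Timp1 (0.737) in 24C_CLP and Cox6c (0.884) in 61M_MSC. In kidney they were Lcn2 (0.817) and Pvalb (0.78) in 100M_MSC, Fpr2 (0.815) and Dlat (0.752) in 77S, Casp4 (0.808) and Slc10a6 (0.888) in 61M_MSC, Ccl3 (0.87) in 24C_CLP and Socs3 (0.774) in 16M_MSC. In heart they were Chil1 (0.842) in 100M_MSC, Casp4 (0.822) in 22S, Plat (0.806) and Irak3 (0.712) in 78S and Zranb3 (0.954) in 16M_MSC. In lung they were Ly6d (0.808), Cxcl13 (0.826) and AA467197 (0.827) in 21S and Il1r2 (0.715) in 22S.

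Mouse 107C_CLP had a mean position over liver, kidney, heart and lung of 0.325 on a scale from sham (0) to CLP/saline (1), whose ends are arm means without the array itself, so that the arms need not average 0 and 1. On this scale the other 4 CLP/saline mice lay between 0.958 and 1.17 and the CLP/MSC mice between 0.416 and 0.806. The CLP/saline end includes 107C_CLP for every mouse but itself, which raises the others and overstates its gap from them. In mean position 0 sham or CLP/MSC mice lay at or above the lowest of the other 4 CLP/saline mice. Within this limit, that argues against a swap with such a mouse. In kidney, though, CLP/MSC mouse 16M_MSC lay at 0.932, above CLP/saline mouse 34C_CLP at 0.881. Failed arrays or poor RNA stay open, as the values do not decide. The deviation of 107C_CLP ran against the CLP effect in each organ. Correlations across genes were -0.804 in liver, -0.887 in kidney, -0.603 in heart and -0.781 in lung (others -0.253 to 0.524). Its low position in part entails such correlations. Its spread off that effect (SD 0.479, 0.323, 0.468 and 0.287) was the largest in 0 of 4 organs. This spread was, however, above the median of the others in liver, heart and lung. A single wrong label and a swap with a mouse outside the series stay open too, and no biological explanation was tested, since the labels give no measure of illness.

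In heart arrays 78S, 34C_CLP, 37C_CLP, 107C_CLP and 16M_MSC, Scgb1a1 stood at 12.64 to 15.28. Lung parenchyma is argued against, because the alveolar genes, Sftpc among them at 5.44 to 8.48, stood at a median of -5.46 log2 from the level that the Scgb1a1 share would bring in the array nearest to it, 107C_CLP. Airway epithelium may be the source, as at least 60% of 10 detected airway genes stood over 1 log2 above the median heart array in each of the 5, against 0 or 10% in the other 10 arrays. Thymus may be present in 78S, where the mean of 8 thymocyte genes stood 2.88 log2 above the median heart array, a result from 1 array. The labels name no such tissue and no biological explanation was tested.

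The spleen array recorded as sham s3, which enters no comparison of the main analysis, had a position of 1.091, above every sham array (highest 0.365), with Saa3 at 12.63 and Lcn2 at 13.89. The array recorded as MSC8 had a position of 0.115, with Saa3 at 7.46. The tables argue against wrong column names in the other table, which would need this array, named sham there, at or above the lowest CLP/saline array (0.327). Wrong arms in the sample records may account for both arrays. The CLP/saline and sham positions overlap between 0.327 and 0.365, and neither of these 2 arrays lies in that range. An error elsewhere in the names stays open. No biological explanation was tested.

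Differences between tissues were tested with each tissue set against the mean of the other 4. The spread per gene was shared by all tissues, so the counts do not rank them. The CLP effect differed for 3756 genes in liver, 1188 in kidney, 1108 in heart, 776 in lung and 620 in spleen, and the MSC effect for 1073, 13, 47 and 15 in the first 4 of these. Among the genes called in all 5 tissues, the liver effect differed by -1.55 for Saa3, -3.78 for Lcn2, 3.78 for Cd14, -1.06 for Fpr2, 1.41 for Pdk4, -2.28 for Socs3, 1.5 for Slc10a6 and -1.84 for Mt2. The kidney effect differed by 2.48 for Lcn2, 1.73 for Fpr2 and 1.29 for Socs3. The heart effect differed by 1.59 for Saa3, 2.23 for Lcn2, -1.89 for Cd14, 1.8 for Fpr2 and 2.05 for Cxcl13. The lung effect differed by -2.3 for Lcn2, -2.48 for Cd14, -1.85 for Fpr2 and -1.92 for Slc10a6, and the spleen effect by -2.28 for Cxcl13 (log2, limma, adjusted p = 2.45e-10 to 0.0459). Lcn2 stood at 16.00 ± 0.03 (SD, n = 5) in CLP/saline liver, at the top of the scale, so its differences in liver, kidney, heart and lung all rest on a bounded value.

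Other splits of the same arrays into arms of the same sizes were fitted to see if chance could give counts as large. For CLP/saline against sham 1 of 100 splits, the real one, reached the real gene count in liver (4781, highest other 3587). The same held in kidney (4404, 4147) and lung (3646, 2339), and 2 of 100 reached it in heart (2001, 2401). Counts as large were thus rare among the splits of these organs, so chance alone is unlikely there. In spleen 2 of 35 did (635, 2160), so chance is not excluded. For CLP/MSC against CLP/saline 6 of 100 did in liver (621, 3177), 100 in kidney (0, 4484), 3 in heart (2, 37), 100 in lung (0, 1959) and 35 of 35 in spleen (0, 3725), so chance is not excluded in liver. The count of 2 in heart rests on little, as it was 0 without any 1 of 10 arrays, without the filter, with averaged probes and with only the compared arms. A count of 0 is reached by any split, so nothing was tested in kidney, lung and spleen. These counts of 0 by limma stood beside 3027 genes in kidney, 2970 in lung and 387 in spleen at an unadjusted p under 0.05. Splits that call several times the real count, as in liver, may reflect a structure of the arrays, which was not tested. For CLP/MSC against sham 1 of 100 did in liver (2306, highest other 17), kidney (791, 0), heart (345, 199) and lung (1135, 0). Chance alone is thus unlikely in these organs. In spleen the 10 splits are too few for a share under 0.05 (260, 0).

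Counts of gene lists under the preset correlation were reached by other splits far more often. For CLP/saline against sham 7 of 100 splits did in liver (16, highest other 18), 29 in kidney (14, 20), 43 in heart (14, 25), 18 in lung (14, 20) and 2 of 35 in spleen (19, 21). For CLP/MSC against CLP/saline 77 of 100 did in liver (5, 19), 55 in kidney (9, 16), 47 in heart (11, 30), 83 in lung (6, 21) and 35 of 35 in spleen (3, 12). For CLP/MSC against sham 6 of 100 did in liver (15, 16), 3 in kidney (22, 24), 9 in heart (23, 29) and 11 in lung (18, 24), and the 10 splits in spleen are too few (1 as large, 20 against 16). Chance is excluded for none of these list counts, with spleen in CLP/MSC against sham undecided. The share was lowest for kidney in CLP/MSC against sham, but other splits gave up to 24 lists there. With an estimated correlation 0 of these kidney lists passed. Splits of 1 tissue remove its effect and so set it apart from the others, and therefore do not test if chance gives a difference between tissues. For the CLP effect 1 of 100 did in liver (3756, highest other 3104), 14 in kidney (1188, 2601), 60 in heart (1108, 4107), 69 in lung (776, 2858) and 18 of 35 in spleen (620, 4574). With the MSC effect 3 of 100 did in liver (1073, 1915), 20 in kidney (13, 3121), 9 in heart (47, 939), 10 in lung (15, 852) and 35 of 35 in spleen (0 genes by limma, 775 at an unadjusted p under 0.05, highest other 3573).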

How the results depend on the processing

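The fits of all 12 spleen arrays, those without arrays holding transcripts of another organ, cyclic loess and the model of 4 organs were chosen after the data were seen, and the other alternatives before. Joint normalization of all arrays and eBayes with trend and robust options moved no count of genes or lists by over 1.5 times, and no scaling moved the share of higher genes by over 10 points. Of 188 named gene changes after CLP, 187 kept their direction and call with joint normalization, 185 with no filter, 186 with only the compared arms and 188 with array weights. All 18 named changes of CLP/MSC against CLP/saline lost their call with no filter and with only the compared arms. Background correction and the slide as a block were not run, because the tables gave no uncorrected signal and no slide, and median scaling was not run, because all arrays of a set had the same quantiles. Signal over background is unknown, so changes near the floor of detection are limited by it. Where no cause is named below, the cause was not tested.

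With the series matrix levels BC048644 changed by 0.17 in liver (adjusted p = 0.562, limma) through another choice of probe, and 8 lists passed for CLP/MSC against CLP/saline in liver. For that comparison no filter left 0 genes in liver and 0 in heart and 1 list in spleen, and a stricter filter gave 939 and 20 genes. A fit of only the compared arms gave 0 genes in liver and 0 in heart there, 1271 in heart for CLP/saline against sham, and 1748 in kidney and 1897 in lung for CLP/MSC against sham. The mean of all passing probes gave 0 genes in heart and 5 lists in spleen for CLP/MSC against CLP/saline, and cyclic loess 1 gene in heart.

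Array weights gave, for CLP/MSC against CLP/saline, 2895 genes in liver, 2997 in kidney, 925 in heart and 1544 in lung, and 9 lists in spleen. They gave, for CLP/MSC against sham, 3747 in liver, 2044 in kidney, 1714 in heart, 1969 in lung and 2685 in spleen, and for CLP/saline against sham 3809 in heart and 3387 in spleen. The spleen interferon list in CLP/MSC against sham then had a median of 0.0635 and turned to a lower direction in camera (adjusted p = 0.68), as it did without MSC7 (median -0.0361, adjusted p = 0.358, and up to 1.22 without MSC5).

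Without arrays holding transcripts of another organ, CLP/MSC against CLP/saline had 0 genes in liver and 1502 in heart, with 5 lists in kidney and 7 in heart. CLP/saline against sham had 2713 genes in kidney and 3628 in heart, and CLP/MSC against sham 519 genes and 14 lists in heart. The heart B cell list changed sign in CLP/MSC against CLP/saline (median 0.107, adjusted p = 0.528), and the hepatocyte list in CLP/MSC against sham (-0.37, adjusted p = 0.767). With arms by the sample records, spleen had 0 genes for CLP/saline against sham, 0 for CLP/MSC against sham, 11 lists for CLP/MSC against CLP/saline and 250 genes with a different CLP effect, while the share with the opposite sign had no value there, since no gene was called after CLP. With arms by the column names it had 1737 and 1017 genes in the first 2 of these, and the MSC effect in kidney differed for 37.

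The mouse as a block came with a joint fit of 4 organs, which also pools their spread. Moves of a count can thus not be put down to the block alone. For CLP/MSC against CLP/saline this fit gave 2752 genes in liver, 1215 in kidney, 558 in heart and 158 in lung, with 2 lists there. It gave 691 in heart and 460 in lung for CLP/MSC against sham and 2062 in lung for CLP/saline against sham. Among named genes Ahsg, Apoc3 and Cd3g lost their call with it, as did 8 of 58 lists in CLP/saline against sham, 7 of 31 in CLP/MSC against CLP/saline and 7 of 78 in CLP/MSC against sham, and no other call of a named gene or list was lost. With no replicate block the CLP effect differed between tissues for 765 genes in kidney, 634 in heart and 432 in lung, and the MSC effect for 614 in liver, 4 in kidney, 20 in heart, 3 in lung and 1 in spleen. Without spleen it differed for 1403 genes in lung after CLP, and the MSC effect for 61 in kidney, 84 in heart and 37 in lung.

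With an estimated correlation camera passed 0 lists in liver, 0 in kidney, 0 in heart, 2 in lung and 1 in spleen for CLP/saline against sham, 0 in all 5 tissues for CLP/MSC against CLP/saline, and 0, 0, 1, 6 and 2 for CLP/MSC against sham. By fry 25, 20, 12, 20 and 14 lists passed in liver, kidney, heart, lung and spleen for CLP/saline against sham. In the same order 4, 0, 0, 1 and 0 passed for CLP/MSC against CLP/saline, and 22, 20, 12, 16 and 12 for CLP/MSC against sham. With the CLP/saline arrays split into 2 parts, a mean of 51.9% of spleen genes had the opposite sign (36.8 to 66.2% over the splits).

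Leaving out 1 array at a time, genes for CLP/saline against sham ranged from 4194 to 5488 in liver, 3371 to 5785 in kidney, 1346 to 3379 in heart, 2854 to 4681 in lung and 106 to 2284 in spleen. For CLP/MSC against CLP/saline they ranged from 0 to 3327 in liver, 0 to 3615 in kidney, 0 to 852 in heart, 0 to 2646 in lung, each highest without 107C_CLP, and 0 to 0 in spleen. Those for CLP/MSC against sham ranged from 1662 to 2979, 404 to 1552, 191 to 562, 780 to 1499 and 62 to 378 in the same order. List counts were 13 to 16, 14 to 19, 13 to 19, 13 to 15 and 19 to 22 for CLP/saline against sham, 4 to 9, 5 to 11, 4 to 13, 4 to 8 and 2 to 9 for CLP/MSC against CLP/saline, and 14 to 16, 19 to 23, 19 to 24, 17 to 22 and 19 to 22 for CLP/MSC against sham. The CLP effect differed between tissues for 3252 to 4271, 713 to 2036, 768 to 1433, 492 to 1125 and 267 to 1103 genes, and the MSC effect for 512 to 2214, 4 to 654, 8 to 132, 0 to 151 and 0 to 52. The share with the opposite sign was 84.3 to 91.3%, 88.2 to 95.4%, 91.5 to 95.9%, 87.4 to 93.3% and 59.4 to 91.9%, and the Y-linked difference -0.131 to 0.0449, 0.031 to 0.16, -0.0703 to 0.0124, -0.0675 to 0.0176 and -0.28 to 0.0425.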

Other observations

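The test of the position of CLP/MSC mice was chosen after the results were seen, and the gene lists below were fixed before.

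In CLP/MSC against sham, gene groups other than those named above differed as well. In liver, antigen presentation genes of MHC class II were lower for 7 of 14 members (median change -0.96), interferon response genes for 9 of 31 with 1 higher (-0.59), and cell cycle genes for 5 of 21 (-0.29). With an estimated correlation these lists had adjusted p = 0.225, 0.42 and 0.42. In kidney, adrenal markers were higher for 4 of 10 (median 1.83, 7 adjusted over the list alone), monocyte and macrophage markers for 4 of 18 (0.48) and fatty acid oxidation genes for 7 of 26 with 1 lower (0.29), each with adjusted p = 0.305 with an estimated correlation. Glucocorticoid response genes were higher for 10 of 22 in heart (median 0.79) and 9 of 22 in lung (0.68), with adjusted p = 0.0548 and 0.06 with an estimated correlation.

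The genes with the smallest p for a difference between tissues, chosen after their values were seen, included Cd63, a membrane protein of lysosomes, with a CLP effect 3.33 ± 0.23 (log2 ± SE) higher in liver than in the mean of the other 4 tissues (limma, adjusted p = 2.15e-17). The chitinase-like Chil1 differed by 3.56 ± 0.35 in heart and by -3.64 ± 0.35 in lung (adjusted p = 4.26e-11 and 2.54e-11, limma). Lsmem1 had a CLP effect different by -3.05 ± 0.29 in heart and an MSC effect different by 1.78 ± 0.29 there (adjusted p = 2.39e-11 and 0.000202, limma). Acsl3, an enzyme that activates fatty acids, had an MSC effect different by 1.57 ± 0.23 in liver (adjusted p = 4.9e-05, limma).

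A hypothesis for the opposite signs of the CLP and MSC differences is that CLP/MSC mice lay nearer to sham than CLP/saline mice. The mean position over 4 organs was 0.596 ± 0.146 in CLP/MSC and 0.943 ± 0.355 in CLP/saline mice (SD, n = 5 each), a difference of -0.347 (two-sided exact permutation test, p = 0.0437, 252 regroupings). By tissue the same exact permutation test gave p = 0.0556 in liver, 0.107 in kidney, 0.0516 in heart, 0.0357 in lung and 0.829 in spleen, and adjusted p = 0.0926, 0.134, 0.0926, 0.0926 and 0.829, so no single tissue passed. The position measures in another form the opposite signs that prompted the hypothesis, on the same arrays, so the test does not bear it out and the hypothesis stays open. The CLP/saline mouse 107C_CLP lay at 0.325, below all 5 CLP/MSC mice, and entered the test. Its own position was taken from a CLP/saline mean without it, so it is not on quite the same scale as theirs.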
